A study of Mus musculus with 24 samples.

How the data were processed

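The samples were HOXA9-immortalized mouse bone marrow cells carrying a vector for IDH1 R132H, untreated or given vitamin C, with IDH1 wild-type cells for MeDIP-seq. Assays were polyA RNA-seq, ChIP-seq for H3K4me1, H3K4me3, H3K27ac, PU.1 and Runx1, MeDIP-seq with an antibody to 5-methylcytidine, hMeDIP-seq for hydroxymethylated DNA, and WGBS after bisulfite conversion, per the labels' protocols. Each of the 24 samples was its own group, so each group held 1 library. Processed files of 18 samples were used. The samples of wild-type cells with vitamin C (MeDIP-seq), untreated mutant cells (hMeDIP-seq) and 4 ChIP inputs were not used here.

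The submitters' processing notes name CASAVA 1.8.2, BWA, Novoalign 3.02.08, SAMtools 0.1.2, 0.1.8 and 0.1.16, Picard and MACS2 2.1.0.2, and the genome build mm10, without their role or order. Which tool counted reads, and the gene annotation, are not given in the sources used here. The RNA-seq files hold a whole-number read count per Ensembl gene and an RPKM value, both deposited by the authors without replicates. RPKM scales the count by gene length and by reads in the library, and the ratio of reads per RPKM between the libraries was 1.28, close to the ratio of total counts. A count of 0 with an RPKM above 0 stood beside 36 genes untreated and 45 with vitamin C, so some deposited counts may be rounded. Further unnamed columns of these files were not used. Of 22371 genes, 21611 were matched to a symbol. The 10 highest genes took 4.91% of counts untreated and 4.21% with vitamin C, led by Eef1a1. Most genes of ribosomal proteins were not analysed here, since only 6 with an Rpl or Rps symbol were measured.

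The histone peak lists carry a p-value or q-value per peak, of at most 1e-05, as the authors deposited it, and which of the 2 it is was not stated. The PU.1 and Runx1 lists carry a score per peak that the authors deposited without a definition. Repeated intervals in these lists were removed, 1159 and 259 for PU.1 and 139 and 337 for Runx1, untreated and vitamin C in that order. Peaks were listed per library. Peak values are the authors' own and were used to rank peaks within a list. The region lists of MeDIP-seq, hMeDIP-seq and WGBS hold positions without values, and their thresholds, directions and the libraries compared were not stated. MeDIP deMRs and WGBS iMRs are attached to the untreated mutant sample, MeDIP iMRs, hMeDIP iHRs and WGBS deMRs to the vitamin C sample, and the mutant MeDIP list to the untreated wild-type sample.

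With 1 library per group no test between conditions was possible. The log2 change was taken as log2 of (RPKM vitamin C + 0.5) over (RPKM untreated + 0.5), for genes with at least 1 RPKM in 1 or both libraries, and genes with a log2 change of at least 1 or at most −1 were counted. A ratio of RPKM has an exact interval from the binomial distribution of its reads between the 2 libraries, and a share has an exact Clopper-Pearson interval, both at 95%. These intervals, and the floor of 3 counts used where the count of a gene was 0, cover counting error only. The RNA libraries are deep enough that the interval of a named gene is narrow next to its change in most cases, and wide for genes with few reads such as Hba-a1 or Il4.

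The 24 gene lists, the rule for named genes, the comparisons and the alternatives were set before the data were examined. The lists covered primary granules, late granules, monocytes and macrophages, stem cells and HOXA9, myeloid transcription factors, cytosine methylation, other 2-oxoglutarate dioxygenases, hypoxia, NRF2, vitamin C transport, p53, proliferation, interferon, immediate early genes, iron and heme, housekeeping, and markers of mast cells and basophils, eosinophils, erythroid cells, megakaryocytes, dendritic cells, B cells, T and NK cells, and fibroblasts. Of the listed genes 5 were not analysed here for want of a matching symbol: Emr1, Cebpd, Rpl13a, Siglec5 and Hbb-b1. Each list's median was ranked among 10000 random lists of the same size, matched on mean expression in 20 bins. The rule named the 12 largest positive and 12 largest negative log2 changes among genes with at least 5 RPKM in 1 or both libraries, a fixed set (Idh1, Idh2, Tet1, Tet2, Tet3, Dnmt1, Dnmt3a, Dnmt3b, Spi1, Runx1, Hoxa9, Kit, Cebpa, Cebpe), up to 4 members per list with the largest change, and the 5 regions or peaks per list with the strongest value or, without one, the greatest length. Genes of the families in the closing observations, and Cpa3, Mcpt8, Hdc and Prss34, fall outside this rule and were chosen after their values were seen. A further family is not reported here. The authors' deposited gene lists were compared by direction and size only, as they were chosen on these libraries.

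Peaks and regions were counted as shared at an overlap of 1 bp. Shares were set beside 1000 random placements of the same lengths on the same chromosomes. Gene positions came from a RefSeq table of GRCm38.p6, the same assembly as mm10, for 10252 of the 10436 measured genes. That table gave spans without strand, so distances of 50 kb ran to the nearest edge of the span, in place of the transcription start that had been planned. Exons and introns were not told apart. The planned search for PU.1 and Runx1 motifs was not run, since it needs a genome sequence that was not used here. Alternatives were pseudocounts of 0.1 and 1 RPKM, no filter or 5 RPKM, centring on the median, a 1.5-fold threshold, overlap over 50% of the shorter interval, peaks above the median score, equal numbers of the strongest peaks, a minimum length of 500 bp, distances of 1 kb between regions and of 10 or 100 kb to genes, and 200 random placements within 5 kb of H3K4me1 peaks. The last was planned for comparisons with peaks and was added for region lists and gene spans after the data were seen. It placed all random regions near H3K4me1 peaks, while the observed regions were taken from anywhere.

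The steps were tested on simulated data: among 10436 simulated genes, 100% of 100 genes changed 4-fold, 0% of 100 genes changed 1.5-fold and 0 unchanged genes were called at 2-fold. Of 100 random lists of 15 genes, 7 fell outside the 2.5th to 97.5th percentile, and a list of 15 genes raised 2-fold reached percentile 100. The simulated counts held counting noise only, with each gene drawn on its own. They therefore say nothing of false calls from variation between libraries or among genes that vary together. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.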

Results

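The series profiled mouse bone marrow cells immortalized with HOXA9, a homeobox transcription factor that keeps myeloid progenitors growing, and carrying a vector for IDH1 R132H. This mutant isocitrate dehydrogenase converts 2-oxoglutarate to 2-hydroxyglutarate, which competes with 2-oxoglutarate in dioxygenases such as the TET enzymes that oxidise methylated cytosine. Vitamin C helps to keep the iron of these enzymes reduced. It was added to 0.345 mM at 0, 24 and 48 h, and the treated cells were harvested at 72 h. The harvest time of the untreated cells was not recorded in the sample labels used here. The question of the series, from its title, was how vitamin C remodels the epigenome of IDH1 mutant acute myeloid leukaemia. The 24 samples formed 24 groups of 1 library, and 18 of them came with processed files: RNA-seq, ChIP-seq for H3K4me1, H3K4me3, H3K27ac, PU.1 and Runx1 with and without vitamin C, and lists of regions from MeDIP-seq, hMeDIP-seq and whole-genome bisulfite sequencing (WGBS). The other 6 samples, 4 of them ChIP inputs, were not analysed here. There were no replicates, so the values compare libraries, not conditions, and no p-value was calculated. The RNA-seq tables summed to 86804487 counts in the untreated library and 111453443 in the vitamin C library. The depth of the ChIP-seq and methylation libraries was unknown.

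The first comparison asked which transcripts differed between untreated and vitamin C-treated IDH1 R132H cells. Fos, an AP-1 subunit of the immediate early response, stood at 0.187 RPKM untreated and 74.5 RPKM with vitamin C, 399-fold higher (95% interval 282 to 582). Egr1, an early growth response transcription factor, went from 0.987 to 88.4 RPKM (89.5-fold, 80.2 to 100.2), Fosb from 0.205 to 26.9 RPKM (131.5-fold) and the phosphatase gene Dusp1 from 5.00 to 69.8 RPKM (14.0-fold). Among the lower genes, Mpo, which encodes the myeloperoxidase of primary granules, was at 796 RPKM untreated and 131 RPKM with vitamin C, 6.10-fold lower. Kit, the receptor for the stem cell factor in the culture medium, was at 32.1 and 5.07 RPKM, 6.32-fold lower (ratio 0.158, 95% interval 0.152 to 0.165).

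Of 10436 genes with at least 1 RPKM in 1 or both libraries, 248 were 2-fold or more higher and 200 were 2-fold or more lower, while 95.7% lay within 2-fold. The log2 changes are on the scale of RPKM plus 0.5, which understates the change of low genes, and their median was −0.04. Other genes far higher with vitamin C were Cxcl2, a neutrophil-attracting chemokine (0.764 to 40.4 RPKM, 52.9-fold), Clec11a, a secreted lectin that acts as a growth factor (1.79 to 68.2 RPKM, 38.1-fold), Cma1, mast cell chymase (0.359 to 14.6 RPKM, 40.8-fold), and Rgs1, a regulator of G protein signalling (0.147 to 10.1 RPKM, 68.4-fold). Fxyd4 was at 0.212 and 9.33 RPKM. Acod1, which makes itaconate, was 11.5-fold higher, the cytokine gene Osm 8.23-fold (11.6 to 95.8 RPKM) and Hmox1, heme oxygenase, 7.80-fold (12.9 to 101 RPKM). Csn2, which encodes the milk protein beta-casein, had 666 reads untreated and 0 with vitamin C, at least 284-fold lower against a floor of 3 reads. Spint2 was at 13.7 and 0.664 RPKM, Gpr65, an acid-sensing receptor, at 11.8 and 0.578 RPKM, and Hpgd, which degrades prostaglandins, at 208 and 20.8 RPKM, 9.98-fold lower (ratio 0.100, 0.0966 to 0.104). The other genes with the largest negative differences were Gm1110, Kcng2, Cpe, Ank, Chd7 and Lipg, with log2 changes from −2.84 for Gm1110 to −2.42 for Lipg. Counting at 1.5-fold gave 648 higher and 693 lower genes, and asking for 5 RPKM left 178 higher and 110 lower genes.

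**Figure D1:**
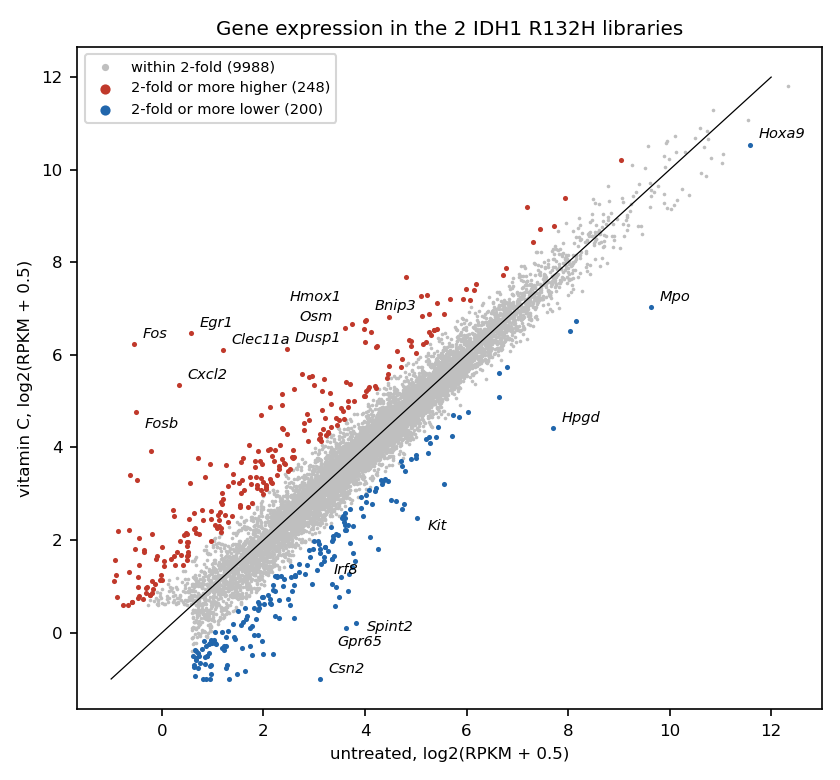
Each point is 1 of 10436 genes, with log2(RPKM + 0.5) of the untreated library on the x axis and of the vitamin C library on the y axis; the line marks equal values. The 248 genes that were 2-fold or more higher are red, the 200 that were 2-fold or more lower are blue, and Fos, Egr1 and Fosb lie farthest above the line.

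Gene lists were compared by the median log2 change of their measured members and by its percentile among 10000 random lists matched on expression. The immediate early list, which handling of cells before lysis can also move, had the highest median, 2.15 (percentile 100). All of its 14 measured members were higher with vitamin C, 10 of them 2-fold or more. Targets of hypoxia and HIF, a factor whose prolyl hydroxylases are themselves 2-oxoglutarate dioxygenases, had a median of 0.67 (percentile 100), with 7 of 19 genes 2-fold or more higher and 0 lower. Examples were Bnip3 (15.8 to 107 RPKM), Ndrg1 (12.5 to 40.8 RPKM), Ankrd37 (3.16 to 8.62 RPKM) and Ddit4 (46.8 to 117 RPKM). The NRF2 and oxidative stress list had a median of 0.38 (percentile 99.99), and 5 of its 18 genes were 2-fold or more higher, among them Hmox1, Nqo1 (3.14 to 9.72 RPKM), Osgin1 (4.45 to 11.6 RPKM) and the cystine transporter gene Slc7a11 (1.95 to 4.73 RPKM). In the iron and heme list the median was 0.58 (percentile 100), with 2 of 11 genes past 2-fold, Hmox1 and the iron exporter gene Slc40a1 (1.56 to 4.54 RPKM). Tfrc, the transferrin receptor, was at 67.7 and 131 RPKM and Fth1, ferritin heavy chain, at 762 and 1465 RPKM. The vitamin C transport list had 3 measured members and a median of 0.81 (percentile 99.87). Slc2a1, which takes up glucose and dehydroascorbate, was at 37.6 and 89.9 RPKM, Slc23a2, a sodium-dependent vitamin C transporter, at 16.4 and 29.1 RPKM, and Slc2a3 at 22.5 and 27.2 RPKM. The p53 and apoptosis list had a median of 0.39 (percentile 99.98), with 1 of 14 genes past 2-fold, the cell cycle inhibitor Cdkn1a (70.2 to 167 RPKM). The housekeeping list itself was at 0.26 (percentile 98.4), with Gapdh 2.08-fold higher.

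Myeloid genes differed in both directions. The primary granule list had a median of −0.35 (percentile 0.39), with 2 of 8 genes 2-fold or more lower, Mpo and the proteinase Prtn3 (285 to 107 RPKM). Ctsg was at 2101 and 1136 RPKM. In the stem cell and HOXA9 list the median was −0.22 (percentile 1.32), and 3 of 17 genes were 2-fold or more lower: Kit, Flt3 (6.97 to 2.95 RPKM) and Hoxa9 (3062 to 1487 RPKM). Reads from the HOXA9 vector and from the endogenous gene were not separated. The monocyte and macrophage list had a median of 0.56 (percentile 100). Of its 14 genes 5 were 2-fold or more higher, including the coagulation factor gene F13a1 (4.64 to 20.9 RPKM), Cd68 (34.3 to 114 RPKM) and Cd14 (16.3 to 38.0 RPKM), and 2 were lower, including Irf8 (8.58 to 2.58 RPKM). Irf8 is a transcription factor of monocyte and dendritic cell development. The list of myeloid transcription factors had a median of 0.20 (percentile 98.5), with Egr1 past 2-fold higher and Irf8 and Gfi1 (52.0 to 18.4 RPKM) past 2-fold lower among 14. Spi1, which encodes PU.1, was at 105 and 83.0 RPKM, Runx1 at 52.5 and 66.3, Cebpa at 198 and 161, and Cebpe at 26.3 and 19.4. The late granule list had a median of 0.31 (percentile 97.46), with 0 past 2-fold among 6 measured genes of 18.

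The cytosine methylation and demethylation list had a median of −0.16 (percentile 13.9), with 1 of 15 genes past 2-fold. That gene was Dnmt3b, a de novo DNA methyltransferase, at 2.54 and 0.681 RPKM. Tet2, one of the 5-methylcytosine dioxygenases, was at 12.8 and 6.45 RPKM, a log2 change of −0.94. Tet3 was at 15.6 and 12.9 RPKM, and Tet1 had 4 and 2 reads, too few for a ratio. Idh2 was at 120 and 72.6 RPKM, Idh1 at 76.2 and 68.3, Dnmt1 at 106 and 98.5 and Dnmt3a at 4.29 and 3.39. Whether Idh1 reads came from the endogenous gene or from the vector was not separated. The other 2-oxoglutarate dioxygenases had a median of 0.01 (percentile 70.1). The 2 of 21 past 2-fold were collagen hydroxylase genes, Plod2 (3.88 to 28.8 RPKM) and P4ha1 (21.4 to 47.5 RPKM), and both belong to the class of genes that hypoxia induces. The proliferation list had a median of 0.13 (percentile 96.1) over 18 measured genes of 19, with 0 past 2-fold. The interferon list had a median of −0.04 (percentile 54.4), also with 0 past 2-fold, but only 8 of its 20 genes were measured. The rest of the interferon list was below 1 RPKM in both libraries.

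Marker lists of other blood cells also stood apart from the random lists in part. The mast cell and basophil list had a median of 0.56 (percentile 99.9), with Cma1, Ms4a2 (1.23 to 5.78 RPKM), Gata1 (1.06 to 4.21 RPKM) and Il4 (21 and 139 reads) 2-fold or more higher among 9. Its members with the highest RPKM stayed within 2-fold: Cpa3 (1863 to 2488), Mcpt8 (110 to 140) and Hdc (46.6 to 60.2). Prss34 was lower (8.40 to 7.28 RPKM). The erythroid list had a median of 0.59 (percentile 99.2) over 5 genes. Its members past 2-fold were the alpha-globin copies Hba-a1 (8 and 311 reads) and Hba-a2 (11 and 227 reads), which share sequence and are uncertain for that reason, while the beta-globin gene Hbb-bs was at 340 and 380 RPKM. Of 4 dendritic genes Cd74 (4.11 to 12.5 RPKM) and Itgax (0.354 to 1.25 RPKM) were higher, H2-Ab1 (1.97 to 0.530 RPKM) and Flt3 were lower, and the median was −0.04 (percentile 61.8), which turned to 0.18 with a pseudocount of 0.1 RPKM. The T and NK cell list had a median of 0.02 (percentile 60.8) over 3 measured genes of 12, with Gzmb, granzyme B, at 15.5 and 76.8 RPKM. The megakaryocyte list was at 0.16 (percentile 86.3) and the fibroblast list at 0.30 (percentile 90.1), each with 0 genes past 2-fold. Of these 2 lists 5 of 10 and 3 of 11 genes were measured. No gene of the B cell or eosinophil lists reached 1 RPKM.

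**Figure D2:**
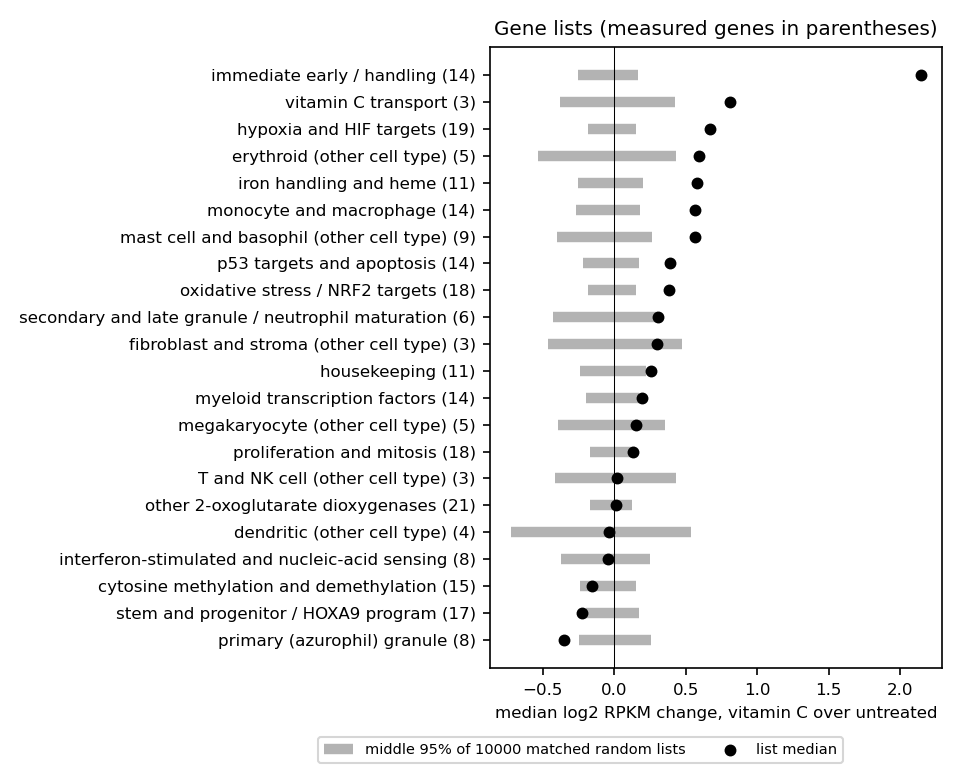
Black points give the median log2 RPKM change, vitamin C over untreated, of each gene list on the x axis, and grey bars the middle 95% of 10000 random lists matched on expression. The immediate early list lies at 2.15 and the primary granule list at −0.35, outside their bars.

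The authors' deposited list of higher genes held 450 genes, all of them higher in these tables, with 244 past 2-fold among 410 measured and a median log2 change of 1.13. The authors' deposited list of lower genes held 221 genes, all lower, with 160 past 2-fold among 180 measured and a median of −1.39. Both lists were chosen on these libraries, so they are not independent evidence of direction. Of the 2-fold genes, 4 higher and 40 lower ones were on neither deposited list. Dnmt3b was among the lower genes not listed.

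The next comparison concerned the regions where cytosine methylation or hydroxymethylation was listed as different. The longest WGBS deMR was a stretch of 1255 bp in Ncf4, a subunit of the neutrophil NADPH oxidase, at chromosome 15, 78242912 to 78244166 (mm10), and the longest WGBS iMR was 1349 bp in Ednrb, the endothelin receptor B gene, at chromosome 14, 103842976 to 103844324. A mutant MeDIP region of 2000 bp lay over the same part of Ednrb, at 103843001 to 103845000. Other long WGBS deMRs were in Dnmbp (1109 bp), Hoxc6 (930 bp), Slc31a2 (904 bp) and Ryr1 (875 bp). The tags deMR, iMR and iHR are the authors' names, and neither the labels nor the files say which way methylation differed or which libraries were compared.

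The mutant MeDIP list, attached to the untreated IDH1 wild-type sample, had 4182 regions over 2.58 Mb. MeDIP deMRs numbered 3789, MeDIP iMRs 4564 and hMeDIP iHRs 7829, each with a median of 500 bp and a shortest region of 250 bp, on the 19 autosomes. WGBS iMRs numbered 8374 with a median of 247 bp, and WGBS deMRs 6496 with a median of 167 bp. Only 603 WGBS iMRs and 228 WGBS deMRs reached 500 bp in length. Spans of protein-coding genes held 59.7% of mutant list regions, 60.0% of MeDIP deMRs and 58.7% of WGBS deMRs, and 50.6% of hMeDIP iHRs, against means of 40.3% to 41.5% for random placements. For MeDIP iMRs the share was 44.4% and for WGBS iMRs 44.3%, against 40.9% and 39.8%. Against random placement within 5 kb of H3K4me1 peaks, an alternative added after the data were seen, the fold for gene spans was 1.03 for the mutant list, MeDIP deMRs and WGBS deMRs, and fell below 1 for hMeDIP iHRs (0.882), MeDIP iMRs (0.771) and WGBS iMRs (0.778). Since the observed regions were not limited to that space, a fold below 1 does not by itself show depletion. Among 5 of the longest regions per list, deMRs of MeDIP lay in Tab1, Hdac7 and Urb1, MeDIP iMRs in Arhgap28, Nav1 and Ak9, and hMeDIP iHRs in Uck2, Spata13, Mcfd2 and Bcl2.

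Lists with the same tag overlapped across assays more often than random placements did, though most of their regions did not overlap. MeDIP deMRs overlapped WGBS deMRs in 176 cases, 4.65% (95% interval 4.00 to 5.36), where random placements averaged 0.209% and reached 0.475% at most. MeDIP iMRs overlapped WGBS iMRs in 58 cases, 1.27% (0.966 to 1.64), against a random mean of 0.272%. hMeDIP iHRs overlapped WGBS deMRs in 208 cases, 2.66% (2.31 to 3.04), against 0.198%, and WGBS iMRs in 0.332%, within the random range up to 0.473%. MeDIP deMRs overlapped MeDIP iMRs in 0 of 3789, with a 95% interval up to 0.0973%. If both tags come from 1 comparison, this 0 holds by construction. Across assays MeDIP deMRs overlapped WGBS iMRs in 0.132%, and MeDIP iMRs overlapped WGBS deMRs in 0.131%, both within their random ranges. The mutant list shared 331 regions with the MeDIP deMRs, 7.91% (7.11 to 8.77), 41.4 times the random mean of 0.191%. It also overlapped WGBS iMRs (102 regions, 2.44%) and WGBS deMRs (113 regions, 2.70%), against random means of 0.284% and 0.211%. Against placement near H3K4me1 peaks the fold was 20.2 for the mutant list with MeDIP deMRs, 9.45 in place of 22.3 for MeDIP with WGBS deMRs, and 5.46 in place of 13.4 for hMeDIP iHRs with WGBS deMRs. For the mutant list it was 5.21 in place of 12.8 with WGBS deMRs and 12.5 in place of 8.58 with WGBS iMRs, and for the iMR pair 6.80 in place of 4.67. Counting regions within 1 kb in place of an overlap gave 2.26% for the iMR pair and 5.10% for hMeDIP iHRs with WGBS deMRs.

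Chromatin marks and transcription factors were then compared between the untreated and vitamin C libraries of the mutant cells. PU.1, the myeloid pioneer factor encoded by Spi1, had 61611 peaks untreated and 23522 with vitamin C. The strongest untreated PU.1 peak, in Jazf1 at chromosome 6, 52842371 to 52843237, scored 687, and the vitamin C list held a peak at the same place with a score of 431. Peaks in Nnmt and near Slc22a28 were likewise in the top 5 of both lists. Runx1 went the other way, with 3908 peaks untreated and 6250 with vitamin C. Its strongest vitamin C peaks lay in Tmem123 (score 271), Pkd1, Tpst2, Pdk1 and Sh2b3, and its strongest untreated peaks included sites in Zfpm1 and Ripk2.

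H3K4me3, a mark of promoters, was listed at 45713 peaks untreated and 48385 with vitamin C, and H3K27ac, a mark of active promoters and enhancers, at 36953 and 35970. Of untreated H3K4me3 peaks 90.5% (90.2 to 90.7) overlapped a vitamin C peak, and of untreated H3K27ac peaks 86.6% (86.3 to 87.0). In both libraries a peak in Hjurp was the strongest H3K4me3 peak, and a peak in Il18r1 was among the H3K27ac peaks with a listed value of 0, of which there were 51 untreated and 40 with vitamin C. H3K4me1, a mark of enhancers, had 57750 and 45657 peaks, and 41.1% (40.7 to 41.5) of the untreated ones were found with vitamin C. Of the 5 strongest untreated H3K4me1 peaks 4 lay at Il1r1 and Il1r2, 1 of them 8190 bp outside Il1r1, and the other lay at chromosome 10, 35016519 to 35016799, 405286 bp from the nearest protein-coding gene, Frk. Those with vitamin C included peaks in Rnf149, Prkar2b, Fgd4 and Kcnq3. Across pairs of overlapping peaks the rank correlation of the listed values was 0.09 for H3K4me1, 0.87 for H3K4me3, 0.82 for H3K27ac, 0.71 for PU.1 and 0.69 for Runx1. Peaks are not independent replicates.

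Of untreated PU.1 peaks 36.1% (35.7 to 36.5) were found with vitamin C, and 95.2% (94.9 to 95.4) of vitamin C peaks were found untreated. The share found with vitamin C went from 6.74% in the lowest decile of untreated scores to 96.0% in the highest. Taking equal numbers of the strongest peaks gave 68.3%, and untreated peaks above the median score gave 59.2%. For H3K4me1 the share was 38.9% in the weakest decile and 39.4% in the strongest. Runx1 peaks were found with vitamin C in 81.8% (80.5 to 83.0) of untreated cases, and 50.7% of vitamin C peaks were found untreated.

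**Figure D3:**
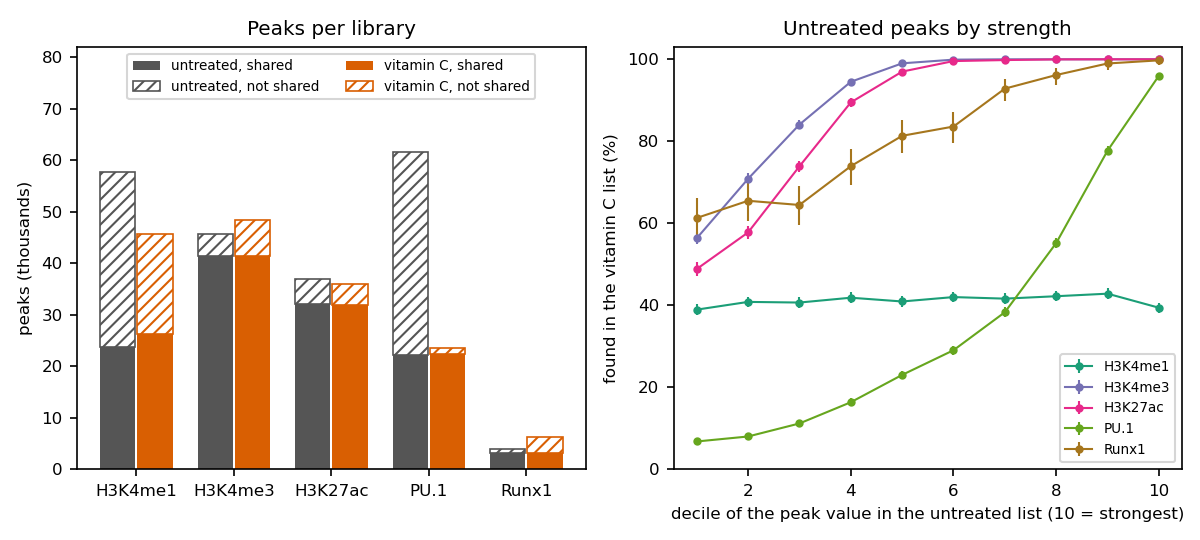
The left panel gives the number of peaks, in units of 1000, per mark and library, with filled bars for peaks that overlap one of the other library and hatched bars for the rest. The right panel gives the percentage of untreated peaks found with vitamin C by decile of the peak value, with exact 95% intervals; PU.1 runs from 6.74% to 96.0% and H3K4me1 stays between 38.9% and 42.8%.

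The region lists were then set against the peaks, which asked where the listed methylation differences lay relative to promoters, enhancers and both factors. WGBS deMRs lay in H3K4me1 peaks of the untreated library in 44.9% of cases (43.7 to 46.1), against a random mean of 7.81%, and in those of the vitamin C library in 30.4% against 4.73%. For H3K27ac the shares were 22.9% untreated and 28.1% with vitamin C, and for H3K4me3 20.3% and 26.6%, against random means between 2.34% and 2.57%. PU.1 peaks held 14.3% of WGBS deMRs untreated and 5.88% with vitamin C, 11.2 and 12.9 times the random means. Runx1 peaks held 0.262% and 0.416% (17 and 27 regions), against random means of 0.0797% and 0.138%.

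Regions tagged iMR were placed differently. WGBS iMRs lay in untreated H3K4me1 peaks in 5.83% of cases, below the random mean of 7.60%, and in untreated H3K4me3 peaks in 8.26%, above 2.54%. MeDIP iMRs were below the random mean in all 10 peak lists: 5.96% lay in untreated H3K4me1 peaks against 8.89%, and 1.38% in untreated H3K27ac peaks against 2.89%. hMeDIP iHRs lay in untreated H3K4me1 peaks in 27.6% and in untreated H3K27ac peaks in 11.9% of cases, against 8.84% and 2.86%. Random placement within 5 kb of H3K4me1 peaks lowered the fold in all 60 comparisons, and 24 went from above 1 to below 1, of which 16 had been outside the random range. The latter included hMeDIP iHRs in untreated H3K4me1 peaks, at 0.885. In untreated H3K27ac peaks hMeDIP iHRs were at 1.30, and WGBS iMRs in untreated H3K4me3 peaks were at 1.01. WGBS iMRs came to 0.642 in untreated H3K27ac peaks and to 1.02 in vitamin C Runx1 peaks. WGBS deMRs kept folds of 1.83 for H3K4me1, 3.29 for H3K4me3, 3.77 for H3K27ac and 5.15 for PU.1 in the vitamin C peaks, while Runx1 came to 0.960. The observed regions were not limited to the space near H3K4me1 peaks, so a fold below 1 here does not by itself show depletion.

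**Figure D4:**
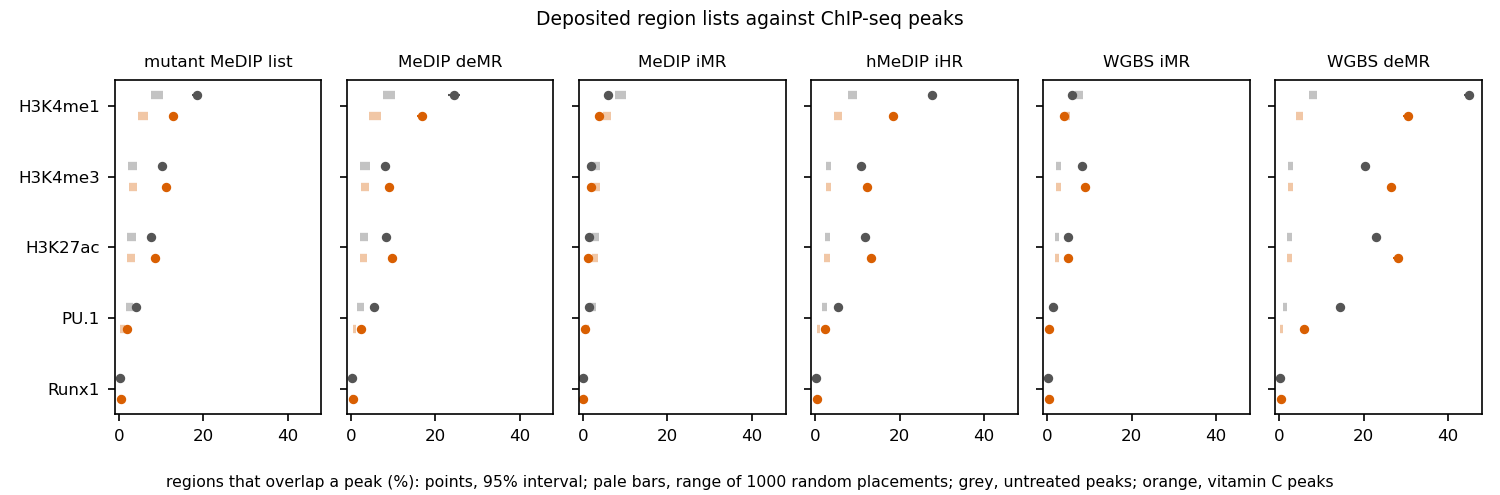
Each panel gives, for 1 region list, the percentage of its regions that overlap a peak of each mark (x axis), with grey points for untreated and orange points for vitamin C peaks and exact 95% intervals. Pale bars span 1000 random placements; WGBS deMRs reach 44.9% in untreated H3K4me1 peaks.

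H3K27ac peaks listed in 1 library only differed in how often they held a WGBS deMR. Of 4040 peaks found with vitamin C only, 6.46% (5.72 to 7.26) overlapped a WGBS deMR, and of 4941 found untreated only, 1.07% (0.804 to 1.40) did. Median lengths of these peaks were 389 and 361 bp. WGBS iMRs lay in 0.371% and 0.506% of them, and hMeDIP iHRs in 2.72% and 0.708%. For H3K4me3 the shares with a WGBS deMR were 5.06% of vitamin C-only and 0.803% of untreated-only peaks, and for PU.1 2.73% and 1.38%. For H3K4me1 the order per peak was the opposite, 2.67% (2.45 to 2.90) and 3.48% (3.29 to 3.68), with median lengths of 896 and 1230 bp. Per Mb of peak this order turned, with 17.7 WGBS deMRs in vitamin C-only and 15.8 in untreated-only H3K4me1 peaks. For H3K27ac these densities were 134 and 24.9 per Mb. For Runx1 the shares were 0.422% and 0.702%, with overlapping intervals (0.225 to 0.720 and 0.228 to 1.63).

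Expression was last compared at genes within 50 kb of the regions. Irf8 had 10 WGBS deMRs and 0 WGBS iMRs within 50 kb, with 16 PU.1 peaks untreated and 6 with vitamin C, and its RPKM was 3.32-fold lower with vitamin C. Over the genome the ratio of PU.1 peak numbers was 0.382, so fewer PU.1 peaks with vitamin C were not particular to Irf8. Runx1 had 11 WGBS deMRs, 7 MeDIP deMRs and 10 hMeDIP iHRs, and was 1.26-fold higher. These counts were not scaled by gene span, and that of Runx1 (92601466 to 92826074) is far longer than that of Irf8 (120736358 to 120756694). Mpo had 2 deMRs in each of the MeDIP and WGBS lists and 4 iHRs, Prtn3 had 2 of each and 5 iHRs, and both were lower. Hoxa9 was the named gene with the most WGBS iMRs, 6, beside 2 WGBS deMRs. Fos had 3 WGBS deMRs, and Egr1 had 0.

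Over all genes near a region list, medians differed little from the random ones. For the 4693 genes near WGBS deMRs the median log2 change was −0.04 (percentile 12.7), with 122 genes 2-fold or more higher and 113 lower. These were 2.60% and 2.41% of them, against 2.16% and 1.51% of the other measured genes, a difference that was not tested. Near the other 5 lists 1.77% to 2.18% of genes were 2-fold or more higher, against 2.51% to 2.68% of the remaining genes, and 1.87% to 2.32% were lower, against 1.75% to 1.95%. Medians were −0.06 near the mutant list (percentile 0.01) and near WGBS iMRs (percentile 0.905), −0.05 near MeDIP deMRs (percentile 0.21), and −0.04 near MeDIP iMRs (percentile 53.6) and hMeDIP iHRs (percentile 55.5), where random lists had a median of about −0.04. At 10 kb the percentiles for MeDIP deMRs and WGBS iMRs came to 11.02 and 20.9, inside the middle 95%. Genes near H3K27ac peaks found with vitamin C only had a median of −0.02 (percentile 99.96), and those near such H3K4me3 peaks −0.03 (percentile 99.95).

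**Figure D5:**
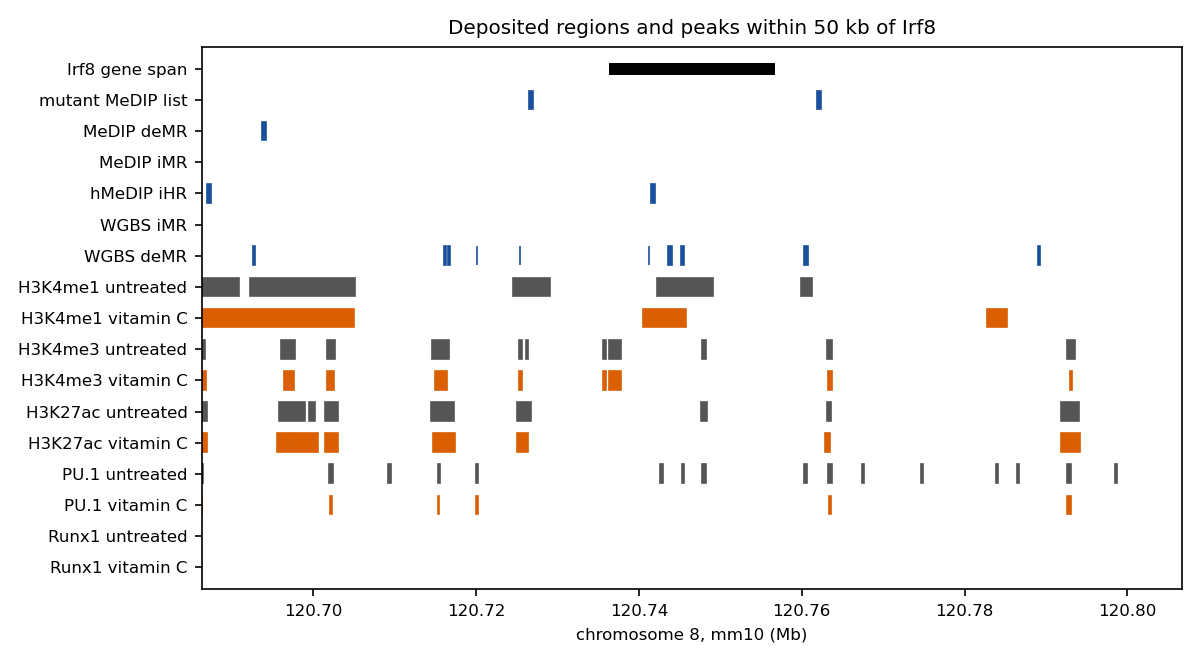
The map shows chromosome 8 (mm10, x axis in Mb) within 50 kb of Irf8, whose span from 120736358 to 120756694 is black; region lists are blue, untreated peaks grey and vitamin C peaks orange. It shows 10 WGBS deMRs, with 16 PU.1 peaks untreated and 6 with vitamin C, where the ratio of PU.1 peak numbers over the genome was 0.382. The locus was picked for drawing after its values were seen.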

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

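Of 44 gene list medians under other pseudocounts, 43 kept their side of the middle 95% of random lists, and 1 passed it that had not before, the late granule list with a pseudocount of 0.1 RPKM (median 0.35). The dendritic list, inside the middle 95% throughout, turned from −0.04 to 0.18 at 0.1 RPKM, and the other 43 values kept their sign. Centring shifted all genes by 0.04, which cannot move a percentile; it turned the dendritic median to 0.0018 and kept the sign of 21 others. Counts of genes moved with the threshold, to 648 higher and 693 lower at 1.5-fold and to 178 higher and 110 lower at 5 RPKM. Under the other settings higher genes numbered 209 to 299 and lower genes 149 to 281.

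Shares of untreated peaks found with vitamin C moved as follows. With 50% of the shorter peak they were 88.9% for H3K4me3 and 85.9% for H3K27ac. Among peaks above the median score they were 41.6% for H3K4me1, 99.98% for H3K4me3, 99.9% for H3K27ac, 59.2% for PU.1 and 94.3% for Runx1, since weak peaks were left out. With equal numbers of the strongest peaks they were 88.6% for H3K4me3, 87.7% for H3K27ac, 68.3% for PU.1 and 69.4% for Runx1.

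At a minimum of 500 bp 603 WGBS iMRs and 228 WGBS deMRs were left. Within 1 kb the mutant list met MeDIP deMRs in 9.21%, MeDIP deMRs met WGBS deMRs in 6.73%, MeDIP iMRs met WGBS iMRs in 2.26% and hMeDIP iHRs met WGBS deMRs in 5.10%. With 50% of the shorter region the last 3 were 3.96%, 0.964% and 2.20%. Shares of WGBS deMRs in vitamin C peaks were 23.1% for H3K4me3, 25.4% for H3K27ac and 5.14% for PU.1 with 50% of the shorter region. With peaks above the median score they were 10.0% for H3K4me1, 14.6% for H3K4me3, 18.4% for H3K27ac, 3.42% for PU.1 and 0.2001% for Runx1.

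Random placement within 5 kb of H3K4me1 peaks lowered the fold in all 60 comparisons with peaks, which follows from placing regions where peaks are dense, and 24 went from above 1 to below 1, 16 of which had been outside the random range. The observed regions were not limited to that space, so folds below 1 do not by themselves show depletion. For WGBS deMRs in vitamin C peaks the folds were 1.83 (H3K4me1), 3.29 (H3K4me3), 3.77 (H3K27ac), 5.15 (PU.1) and 0.960 (Runx1). For the mutant list they were 0.584 and 0.648 in H3K4me1, 0.815 and 0.936 in H3K27ac and 0.762 and 0.884 in PU.1 peaks, untreated and vitamin C in that order. For MeDIP deMRs they were 0.773 and 0.855 in H3K4me1, 0.802 and 0.896 in H3K4me3, and 0.912 in untreated H3K27ac. For hMeDIP iHRs they were 0.885 and 0.944 in H3K4me1, and for WGBS iMRs 0.642 and 0.631 in H3K27ac. The same placement, added after the data were seen, gave folds of 20.2 for the mutant list with MeDIP deMRs, 9.45 for MeDIP with WGBS deMRs, 6.80 for MeDIP with WGBS iMRs and 5.46 for hMeDIP iHRs with WGBS deMRs, and of 0.882, 0.771 and 0.778 for hMeDIP iHRs, MeDIP iMRs and WGBS iMRs in gene spans. Genes within 10 kb had a median of −0.050 near MeDIP deMRs (percentile 11.02) and −0.058 near WGBS iMRs (percentile 20.9), no longer outside the middle 95% of random lists; the cause was not tested.

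The motif search and its alternative with longer words were not run, and a stricter part of each region list could not be formed without values. Depth was known for RNA-seq only. No paired analysis was possible because each group held 1 library.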

Other observations

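The PU.1 detection limit, the yield of all vitamin C ChIP libraries, the ease of calling regions in vitamin C-only peaks and the random draws of vitamin C-only H3K27ac peaks were tests chosen only after the result was seen, and so were the gene families. Chemokine and interleukin genes were the family with the highest median, 1.45 (percentile 100), with 9 of 15 genes 2-fold or more higher. Beside Cxcl2 these included Ccl6 (3.36 to 25.4 RPKM), Il6 (6.90 to 45.4 RPKM) and Cxcl3 (0.0271 to 2.48 RPKM). Histone genes went both ways around a median of 0.00 (percentile 89.0), with 8 of 64 higher, such as Hist1h2bg (8.44 to 36.9 RPKM) and Hist1h1c (18.4 to 72.8 RPKM), and 4 lower, such as H1fx (9.95 to 2.64 RPKM).

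Other families had smaller medians. Subunits of mitochondrial complex I had a median of −0.34 (percentile 0), with 6 of 36 above 0 and 0 past 2-fold: Ndufb7 was at 28.4 and 17.9 RPKM and Ndufs7 at 58.3 and 38.5 RPKM. Zinc finger genes had a median of −0.24 over 274 genes (percentile 0). Solute carriers were at 0.10 over 168 genes (percentile 100) and V-ATPase subunits at 0.23 over 15 (percentile 99.4). Inside the middle 95% of random lists were subunits of the proteasome (percentile 56.8) and the chaperonin (23.4), translation initiation factors (4.54), aminoacyl-tRNA synthetases (56.3), cathepsins (95.1) and tubulins (81.0). H3K27ac peaks overlapped an H3K4me1 peak in 64.4% of cases untreated and 43.8% with vitamin C. The H3K4me1 lists themselves spanned 183 Mb untreated and 108 Mb with vitamin C, which was not corrected for. H3K4me1 was the mark whose shared peaks did not become more frequent with strength.

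PU.1 peaks were fewer with vitamin C, with a ratio of peak numbers of 0.382. A lower yield of all vitamin C ChIP libraries is argued against by Runx1, whose ratio was 1.60, and by H3K4me3 (1.06) and H3K27ac (0.973), while H3K4me1 was at 0.791. A detection limit of the vitamin C PU.1 library may account for the pattern, since 96.0% of the strongest decile of untreated peaks and 6.74% of the weakest decile were found with vitamin C. A loss of PU.1 from weaker sites would give the same order and stays open; Spi1 itself was at 105 and 83.0 RPKM.

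The mutant MeDIP list and the MeDIP deMRs shared 331 regions. Both may draw on the untreated mutant MeDIP library, where chance excess signal would put the same places on both lists. As the cause of all shared regions that is argued against by WGBS, made from other libraries. A WGBS deMR overlapped 30 of the 331 shared regions, 9.06% (95% interval 6.20 to 12.7), where random placements reached 1.51% at most. For shared regions without a WGBS deMR the test cannot decide, since it rests on that overlap. WGBS iMRs overlapped 0 of 331, with a 95% interval up to 1.11%. WGBS deMRs overlapped 2.16% of regions on the mutant list only and 4.13% (3.49 to 4.85) of those on the deMR list only. Both shares were also above all their random placements, so random placement alone does not set the shared regions apart. The interval of the shared regions lay above those of both parts. WGBS iMRs lay in 2.65% (2.16 to 3.21) of regions on the mutant list only, an interval that overlaps that of WGBS deMRs there (1.72 to 2.66), with random means of 0.282% and 0.208%. They lay in 0.144% of regions on the deMR list only. The direction of these lists is not stated, and no biological explanation was tested.

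H3K27ac peaks found with vitamin C only held WGBS deMRs in 6.46% of cases, against 1.07% of untreated-only peaks. Easier calling of regions of either tag in vitamin C-only peaks would raise WGBS iMRs too, but their shares were 0.371% and 0.506%, a ratio of 0.734 and at most 1.87 by the interval bounds, where that of deMRs was at least 4.08. Promoters are argued against as the whole cause, since outside H3K4me3 peaks the shares were 6.68% (5.70 to 7.76) of 2352 and 0.406% (0.186 to 0.770) of 2215. Easier calling of deMRs alone was not tested and stays open, as does a link between the deMRs and the acetylation.

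The other tests, of what might follow from these patterns, were set before their results were seen. If such peaks went with higher expression, the genes near them would stand out: the median of 389 genes within 50 kb was 0.00, at percentile 98.2, and above the −0.03 near vitamin C-only H3K27ac peaks without a WGBS deMR, so both bounds set for it were met. The genes near peaks without a deMR were themselves at percentile 99.58, however, and 133 of 1000 random draws of 261 vitamin C-only peaks gave a median as high. Of the 389 genes 16 were 2-fold or more higher (4.11%) and 17 lower (4.37%). Near vitamin C-only peaks without a deMR these shares were 3.01% and 2.27%, both smaller, a difference that was not tested. A part of the deMRs in the higher median cannot be told apart from that of the peaks alone. If sites with a WGBS deMR kept PU.1 more often, more of their PU.1 peaks would be found with vitamin C than at matched scores. Of 933 such peaks 41.6% were found, against a mean of 39.8% over the random draws. The highest draw, 43.4%, was the bound set for a preference, and the lowest was 36.5%. That bound was not passed, but a small preference could stay below it and is not excluded.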
